A study of Bacillus subtilis subsp. subtilis str. 168 with 2 samples.

How the data were processed

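Gene expression was measured in germinating spores of the Gram-positive soil bacterium Bacillus subtilis on 2 two-colour Agilent oligonucleotide arrays. PROTECT was an experiment in which dried spores were exposed outside the International Space Station, either to open space or to simulated Martian conditions, while control spores stayed on Earth. Per the labels' protocols, spores were first heated for 30 min at 70 °C to activate them and then germinated at 37 °C in rich medium with 10 mM L-alanine, a germinant. They were harvested after 60 min of germination, and 20 µg of total RNA per sample was converted into Cy3- or Cy5-labelled cDNA. Each array compared 1 exposed sample with an Earth control, so there was 1 array per exposure, with no replicate and no dye swap.

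The deposited scanner files held spot intensity values in the Cy3 and Cy5 channels, per the file headers, as mean spot and median local background brightness. Per the file headers, they were written by Feature Extraction 10.1.1.1 with protocol GE2-v5_10_Apr08. The same files held background-subtracted, detrended and dye-normalized processed intensity values and a log10 ratio of Cy5 over Cy3, per the file headers. Other deposited columns held spot flags of 0 or 1, for instance for spots well above background, saturated or non-uniform, per the file headers. The authors' deposited value table held log10 values, 1 column per array and 1 value per gene, with scale and direction unstated. Set against the scanner files, each column equalled the mean log10 ratio of Cy5 over Cy3 over the spots of a gene, without centring. The column medians were -0.05 and -0.04 on the log2 scale for the columns labelled Space and Mars.

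The value table and the scanner files carried opposite labels. The column labelled Space differed by at most 0.0148 (log2) from the scanner file filed under Mars (r = 1 across 4102 genes) and by up to 4.68 from the file filed under Space (r = 0.867). The column labelled Mars differed by at most 0.0141 from the scanner file filed under Space. Neither source says which is right. The arrays are therefore named by the sample under which the scanner file was deposited, as the Space-filed and the Mars-filed array, and any statement on one exposure holds for the other if the value table is right.

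The direction of the ratios is not settled either. Per the labels, the exposed RNA carried Cy3 and the Earth RNA Cy5 on both arrays. The authors' deposited values, titled as exposed against Earth, were Cy5 over Cy3 with the sign as scanned. With the dyes as labelled, a gene higher in Cy5 was higher in the Earth control. With the deposited values read as titled, it was higher in the exposed sample. All ratios are given as Cy5 over Cy3, which departs from the direction of exposed over Earth planned before the data were examined, and no value was used to decide between these readings.

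Spots were corrected for background with limma 3.58.1 (R 4.3.3) by normexp with an offset of 50, and normalized within each array by loess, with control spots and outlier spots at weight 0. Outlier spots (47 on the Space-filed and 30 on the Mars-filed array among gene spots) were then left out, the spots of a probe were averaged, and a gene took the median of its probes. Most genes (4012 of 4102) had 2 probes. A gene counted as apart where its log2 ratio was at least 1 in size, it was well above background in at least 1 channel, and its probes lay on the same side of 0. The difference between arrays was the Space-filed minus the Mars-filed log2 ratio, and a dye effect common to both arrays drops out of it. A gene not above background in a channel has only a bound there, given as at least N-fold. That bound sets the bright channel against the lowest signal among probes well above background or the dim signal itself, whichever was higher, after loess and Aquantile scaling, and stays open to dye bias. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

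No test was possible with 1 array per group, so genes were counted by size only and no p-value is given. The SD between the spots of a gene on an array is given after ±, mostly over 4 spots, and measures technical error only. It pools the spots of all probes of a gene, outlier spots included, so it also holds differences between probes. For a difference between arrays, ± is the root of the summed squares of the SDs of the 2 arrays. The number of arrays limits precision. In simulated arrays of 4102 genes with 200 changed genes, genes changed 2.5-fold were called in 96% of cases for the Space-filed and 88% for the Mars-filed array. Genes changed 8-fold were called in 100% and 92%. None of 50 genes changed 1.5-fold and none of 3902 unchanged genes was called on either simulated array. These simulations hold no variation between cultures and no dye effect particular to a gene or probe, so they cannot give a rate of false calls for the real arrays. Their noise on log2 signals had an SD of 0.12. Real probes of a gene differed in log2 ratio with an SD of 0.25 on the Space-filed and 0.27 on the Mars-filed array.

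Before the data were examined, 35 gene lists were fixed from textbook knowledge, of pathways, stress regulons, mobile elements and markers of sporulating, dormant or stationary cells. They were SOS response, other DNA repair, prophages PBSX and SP-beta, skin element, ICEBs1, general stress (SigB), oxidative stress, protein quality control, envelope stress (SigW), ribosomal proteins, translation factors, purine, pyrimidine, branched-chain amino acid, histidine-tryptophan-arginine and sulfur amino acid synthesis, iron (Fur), tricarboxylic acid cycle, glycolysis, respiration, anaerobic genes, motility, competence, small acid-soluble spore proteins, spore coat, other sporulation genes, germination, cell wall and division, chromosome replication, fatty acid synthesis, cold shock, antibiotics, extracellular and transition-state genes, and stable RNA. Of 825 names given singly, 697 matched a symbol, since older names were not always found, and polYB, listed under an older name, thus fell out of the SOS list. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. It stood apart where it lay below the 2.5 or above the 97.5 percentile. The stable RNA list had 1 measured gene and was not compared.

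Named genes were also fixed by rule beforehand. They were the 12 highest and 12 lowest named genes per array among those counted and above background in both channels, 5 and 5 for the difference between arrays, and up to 4 members per list with the largest ratios. Added to these were recA, lexA, uvrA, sigB, katA, perR, hag, sspA, sspB, ftsZ, rpoB and gapA whatever their values. The files give locus tags, of which 4034 of 4102 had a symbol in a RefSeq gene table of assembly ASM904v1. No genome build is named in the sources used here, so that table served for names and gene order only. For 1 probe sequence the array carried more than 1 gene.

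Both arrays use an Earth control and could share its RNA, so unchanged samples against 1 shared control were simulated 100 times, and their correlation and overlap are given beside the observed ones. The alternatives were the scanner software's processed signals with loess, no background subtraction, an offset of 0, median centring, the software's log ratio, the authors' value table, stricter and no filters on dim probes, the mean over probes, outlier spots kept, other fold sizes, no demand that probes lie on 1 side, and random lists not matched on signal. The value table with its columns matched to the scanner files was added after seeing the data. Spike-in control probes were left out of the comparisons.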

Results

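Spores carried on the PROTECT experiment were germinated on Earth, and their RNA was compared with that of Earth control spores to ask which transcripts differed after exposure to space or to simulated Mars. The data were 2 two-colour arrays, 1 per exposure. Each array held 15744 spots, of which 15208 were probes for 4102 genes. On the Space-filed array 97.4% of gene spots were well above background in Cy3 and 94.6% in Cy5, and on the Mars-filed array 99.4% and 99.9%. Duplicate spots differed with an SD of 0.17 and 0.15 (log2) on the Space-filed and Mars-filed arrays. There was no replicate array, so differences are sizes without a test. Values are log2 of Cy5 over Cy3. Per the labels Cy5 held the Earth control, while the deposited values read as titled would put the exposed sample there, so every direction below is that of the dyes and turns with the reading taken.

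On the Space-filed array, list medians of late spore proteins, oxidative stress, the SP-beta prophage and protein quality control were the highest in Cy5. The gene of the Clp protease ATPase subunit clpE had the highest ratio (5.58 ± 0.13). The genes of fructose use, which were in no fixed list, followed, with the transporter fruA at 5.47 ± 0.11, the kinase fruK at 5.29 ± 0.39 and the regulator fruR at 4.74 ± 0.18. Genes for mannose use were lowest, with the regulator manR at -2.79 ± 0.49 and the isomerase manA at -2.43 ± 0.50. In all, 351 of 4072 measured genes were at least 2-fold apart, 254 higher in Cy5 and 97 lower, and 79 were at least 4-fold apart. With the scanner software's log ratio the count was 457, with 293 higher and 164 lower.

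Among the spore genes, 9 of 16 small acid-soluble spore protein genes, which encode abundant proteins of the dormant spore, were at least 2-fold higher in Cy5 and none was lower. Their median was 1.41, against a random range of -0.30 to 0.32. Members included sspN at 3.67 ± 0.38, sspE at 2.34 ± 0.14, sspJ at 2.22 ± 0.02, sspM at 2.19 ± 0.11 and sspA at 1.44 ± 0.04, while the probes for sspB disagreed (0.17 ± 1.17). The related gene sspT reached 3.71 ± 0.33. Of 54 spore coat genes, 10 were higher and none lower, with cotX at 3.58 ± 0.34 and cgeB at 2.53 ± 0.17, but the list median of 0.13 lay within the random range, though above it with median centring (0.34), the software's log ratio and the matched value table (0.16 each). The probes of cotG (4.17 ± 1.05) and cotV (3.25 ± 0.92) differed widely in size. Also among the highest were yfhD (4.22 ± 0.25), yqfX (4.09 ± 0.32) and ykzE (3.55 ± 0.08).

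Protein quality control genes had a median of 0.57, with 9 of 22 higher in Cy5 and none lower, among them the protease subunit clpP (2.35 ± 0.09), clpC (1.67 ± 0.15) and mcsB (1.47 ± 0.08). Of 21 oxidative stress genes 8 were higher and 1 lower (median 0.73). They included mrgA, a DNA-protecting ferritin-like protein (2.74 ± 0.13), the vegetative catalase katA (2.60 ± 0.16) and the heme synthesis genes hemX (1.59 ± 0.07) and hemA (1.51 ± 0.04), while their repressor gene perR was at 0.76 ± 0.09. The SP-beta prophage, which sits in the chromosome, had 45 of 155 genes higher and 2 lower (median 0.61, random range 0.10 to 0.23). Its highest was yonX at 4.80 ± 0.33, followed by yopA at 2.96 ± 0.03 and yonU at 2.92 ± 0.14. For yosF, whose Cy3 signal was not well above background, the ratio was at least 6.30-fold.

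DNA damage genes were shifted less on this array. Of 28 SOS genes, which the repressor LexA controls, 3 were higher and none lower (median 0.37, random range -0.21 to 0.23), with the recombinase recA at 1.22 ± 0.04, the excision nuclease subunit uvrA at 1.07 ± 0.12 and lexA at 0.06 ± 0.11. Other repair genes had a median of 0.39, with 4 of 35 higher and none lower, such as the Holliday junction resolvase recU (1.55 ± 0.17), the diadenylate cyclase disA (1.41 ± 0.10) and radA (1.37 ± 0.05). Ribosomal protein genes had a median of 0.37 above their random range of -0.28 to 0.08, although only 1 of 55 reached 2-fold. The list was split, with 31 of 55 genes above 0 and quartiles of -0.38 and 0.81.

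Iron uptake genes under Fur were lower in Cy5 (median -0.78, 0 of 22 higher and 5 lower), with the siderophore-binding fhuD at -1.36 ± 0.09 and the bacillibactin gene dhbB at -1.24 ± 0.25. Only 22 of the 48 names fixed for this list were matched to a gene. Fatty acid synthesis genes had a median of -0.51 with 4 of 17 lower and none higher, among them the dehydratase fabZ (-1.60 ± 0.13) and the acyl carrier protein gene acpA (-1.18 ± 0.05). The other lowest genes included glpT (-1.87 ± 0.13) and glpQA (-1.80 ± 0.05) of glycerol phosphate metabolism, the nucleoid protein gene hbs (-1.87 ± 0.09), the cold shock gene cspB (-1.71 ± 0.03), the phosphotransacetylase gene pta (-1.67 ± 0.11) and the competence pheromone gene comX (-1.79 ± 0.49). The genes ycdA (-1.88 ± 0.39), yukE (-1.85 ± 0.04), frxB (-1.84 ± 0.09) and sxzY (-1.67 ± 0.07) completed this group. In 13 of the 351 genes 1 channel was not above background. Which exposure this array represents depends on whether the scanner file or the value table is labelled correctly.

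On the Mars-filed array the SOS response, late spore proteins and the SP-beta prophage had the highest list medians in Cy5. The gene of the error-prone DNA polymerase polYB and its neighbours, of which yqjX, yqjY and yqjZ but not polYB and yqkA were matched to the fixed SOS list, stood at 5.38 ± 0.18 (polYB), 5.64 ± 0.02 (yqjX), 5.32 ± 0.15 (yqjY), 5.09 ± 0.26 (yqjZ) and 4.98 ± 0.22 (yqkA). In SP-beta, yonX reached 6.33 ± 0.25 and yonU 5.15 ± 0.09, and spbT, next to yonU but in no fixed list, 5.96 ± 0.16. The genes clpE (5.64 ± 0.15), fruK (5.31 ± 0.32), fruA (5.17 ± 0.15) and fruR (4.48 ± 0.17) were again among the highest. In all, 619 of 4102 genes were at least 2-fold apart, 376 higher in Cy5 and 243 lower, and 141 were at least 4-fold apart.

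Of the 28 SOS genes, 18 were higher in Cy5 and none lower (median 1.46, random range -0.28 to 0.33). The gene recA was at 2.95 ± 0.07, uvrA at 3.12 ± 0.08 and lexA at 0.67 ± 0.22. For uvrX the spots disagreed (3.28 ± 2.28) by more than its probe values of 2.20 and 4.35 alone would give. Other repair genes had a median of 0.53, with 10 of 35 higher and 1 lower, such as radA (2.12 ± 0.07), recU (2.03 ± 0.12), addB of the AddAB helicase-nuclease (1.94 ± 0.17) and disA (1.89 ± 0.20). SP-beta genes had a median of 0.97, or 1.46 with the scanner software's background and loess, with 73 of 155 higher and 7 lower, including yopA (3.88 ± 0.08) and yosF (3.73 ± 0.10). Chromosome replication genes had a median of 0.51 and 3 of 19 were higher, namely dnaN (1.16 ± 0.07), priA (1.15 ± 0.15) and dnaA (1.02 ± 0.11). The RNA polymerase gene rpoB was at 1.22 ± 0.05.

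Oxidative stress genes had a median of 0.59, with 9 of 21 higher and 2 lower in Cy5, and mrgA (4.45 ± 0.19), katA (3.18 ± 0.14), hemX (3.10 ± 0.07) and hemA (2.92 ± 0.06) led them, while perR was at 0.28 ± 0.17. Protein quality control genes had a median of 0.93 and 11 of 22 were higher, with clpC at 2.53 ± 0.18, mcsB at 2.23 ± 0.12 and clpP at 1.80 ± 0.03. Of the 16 small acid-soluble spore protein genes 9 were higher (median 1.07), with sspN at 3.59 ± 0.07, sspJ at 2.16 ± 0.19, sspM at 2.16 ± 0.36, sspE at 1.09 ± 0.14 and sspA at 1.05 ± 0.09. Coat genes had a median of 0.33, above their random range of -0.18 to 0.23, with 15 of 54 higher and none lower, among them cotX (3.77 ± 0.40) and cgeB (2.96 ± 0.16). Germination genes had a median of 0.42, above their random range of -0.27 to 0.31. Of them 2 of 25 were higher, gerPE (1.22, whose spots differed by less than the rounding) and gerPD (1.13 ± 0.18).

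Fatty acid synthesis genes were lower in Cy5, with a median of -0.96 and 8 of 17 lower, including fabZ (-2.17 ± 0.14), the enoyl reductase fabI (-2.08 ± 0.20), plsC (-1.75 ± 0.04) and acpA (-1.64 ± 0.12). Iron genes had a median of -0.86 with 7 of 22 lower, such as fhuD (-2.12 ± 0.11), ykuO (-2.10 ± 0.10), hmoA (-1.47 ± 0.02) and dhbB (-1.21 ± 0.23), and the flavodoxin gene fldN was at -2.26 ± 0.18. The lowest genes were frxB (-2.91 ± 0.17), cspB (-2.60 ± 0.06), sxzY (-2.54 ± 0.08), hbs (-2.35 ± 0.05), walL (-2.29 ± 0.09), pta (-2.23 ± 0.13), manA (-2.23 ± 0.30), yukE (-2.21 ± 0.08), manR (-2.21 ± 0.16) and rtbE (-2.19 ± 0.41). With median centring in place of loess, 1005 genes were at least 2-fold apart on this array, 600 higher in Cy5 and 405 lower. The medians of SP-beta, coat and other sporulation genes were then 1.82, 0.75 and 0.59, and those of oxidative stress, other repair and replication genes 0.31, 0.30 and 0.25.

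**Figure D1:**
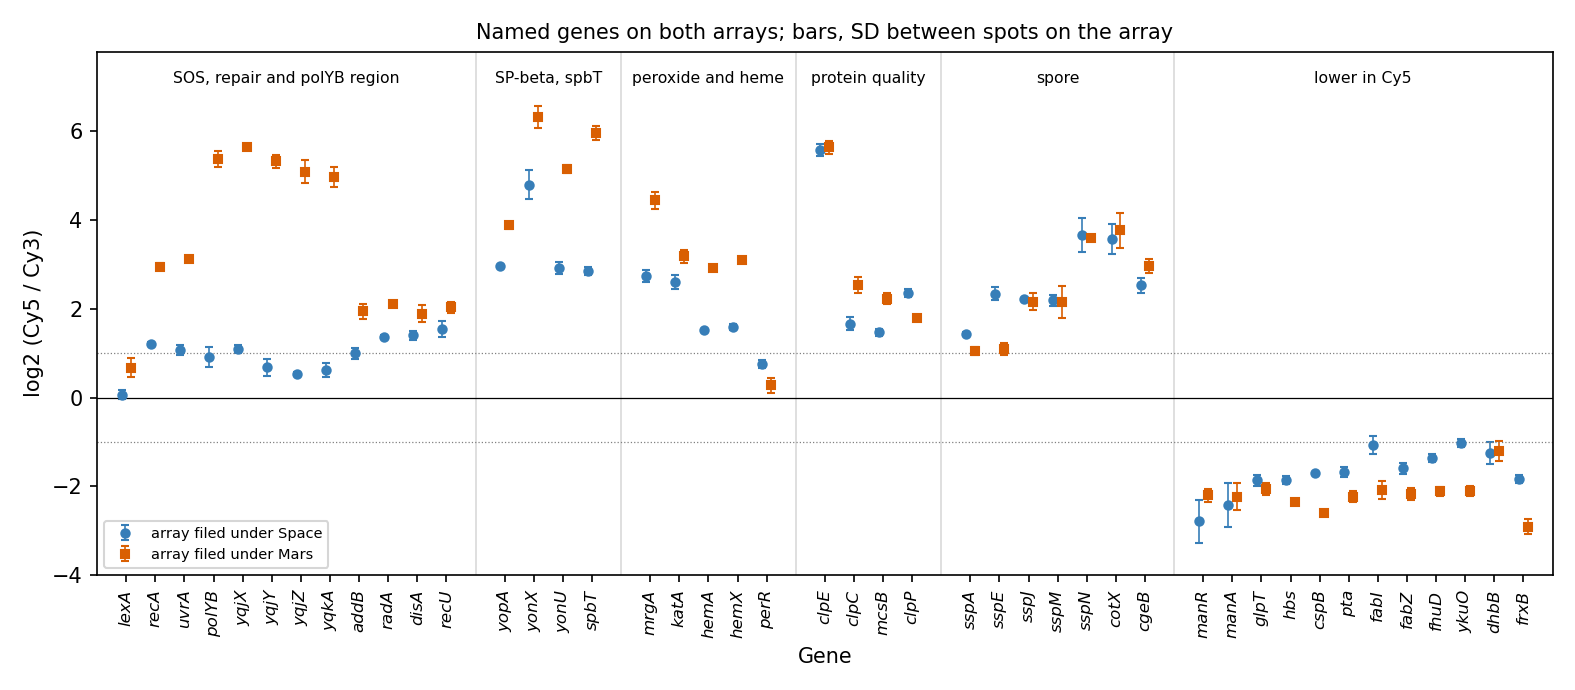
Log2 ratio of Cy5 over Cy3 (vertical axis) for named genes (horizontal axis), as blue circles on the Space-filed and orange squares on the Mars-filed array, with the SD between spots as bars and dotted lines at 1 and -1. The genes polYB to yqkA, of which polYB and yqkA were in no fixed list, as was spbT, lie between 4.98 and 5.64 on the Mars-filed array and between 0.53 and 1.09 on the Space-filed array, while clpE lies at 5.64 and 5.58.

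Several further lists stood apart on at least 1 array. Purine genes were lower in Cy5 on both, with medians of -0.36 and -0.53 on the Space-filed and Mars-filed arrays, and purA of AMP synthesis was at -1.32 ± 0.10 and -1.76 ± 0.13. Extracellular and transition-state genes had medians of -0.23 and -0.25, the latter within the random range under 4 of 12 alternatives, with the response regulator gene degU at -1.20 ± 0.11 and -1.62 ± 0.13 and the repressor gene abrB at -0.82 ± 0.11 and -1.74 ± 0.13. Other sporulation genes had medians of 0.20 and 0.26, with spoVIF at 1.39 ± 0.42 and 1.45 ± 0.50. Tricarboxylic acid cycle genes (-0.43 and -0.09) and anaerobic genes (-0.36 and -0.29) lay below the random range on the Space-filed array and within it on the Mars-filed array, with odhA at -1.02 ± 0.10 and -0.79 ± 0.09 and narH at -0.85 ± 0.15 and -0.55 ± 0.12. Ribosomal protein genes, at a median of 0.15 on the Mars-filed array, lay within their range there, but above it under 3 of 11 alternatives that kept the array labels. Of them 10 of 55 were lower, such as rpsT (-1.64 ± 0.06). Replication genes on the Space-filed array (median 0.31) lay just above theirs, but within it under 6 of 12 alternatives.

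With the main settings the remaining lists had medians within the random range on both arrays, given in the order Space-filed and Mars-filed. Germination genes, given with them for the Space-filed array, lay above the range on the Mars-filed array. Among mobile elements, prophage PBSX had 0.19 and 0.27 with 0 of 31 genes past 2-fold, the skin element 0.31 and 0.30, and ICEBs1 0.24 and 0.32. General stress genes under SigB had -0.12 and -0.10, with sigB at -0.45 ± 0.04 and 0.03 ± 0.08, dps at -1.21 ± 0.10 and -1.63 ± 0.25, and yjbC at 2.06 ± 0.05 and 1.62 ± 0.09. Envelope stress genes under SigW had 0.16 and -0.03, with floA at 1.22 ± 0.10 and 1.51 ± 0.16. Translation factor and synthetase genes had -0.09 and -0.19, with serS at -1.40 ± 0.18 and -1.81 ± 0.20. Pyrimidine genes had -0.07 and -0.10, branched-chain amino acid genes 0.11 and 0.16, histidine, tryptophan and arginine genes 0.05 and 0.05, and sulfur amino acid genes 0.10 and 0.05. Glycolysis genes had -0.33 and -0.38, with gapA at -0.54 ± 0.03 and -0.77 ± 0.05, and respiration genes -0.05 and 0.02, with ctaF at 1.11 ± 0.32 and 1.52 ± 0.43.

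Motility genes had medians of 0.07 and 0.16, with the flagellin gene hag at 0.03 ± 0.14 and -0.10 ± 0.15, and the probes for fliL disagreed (2.11 ± 1.91 on the Mars-filed array). Competence genes had 0.11 and 0.14, germination genes 0.19 on the Space-filed array, where 4 of the 11 alternatives that kept the labels put them above the range, and cell wall and division genes 0.07 and 0.16, with ponA at 1.43 ± 0.07 and 1.64 ± 0.08 and ftsZ at 0.47 ± 0.16 and 0.27 ± 0.11. Cold shock genes had 0.07 and -0.25 and antibiotic synthesis genes -0.12 and -0.15, of which the Space-filed median lay below the range under 6 of these 11 alternatives. The single stable RNA gene, trnE, was at 0.38 ± 0.16 and -0.02 ± 0.11.

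**Figure D2:**
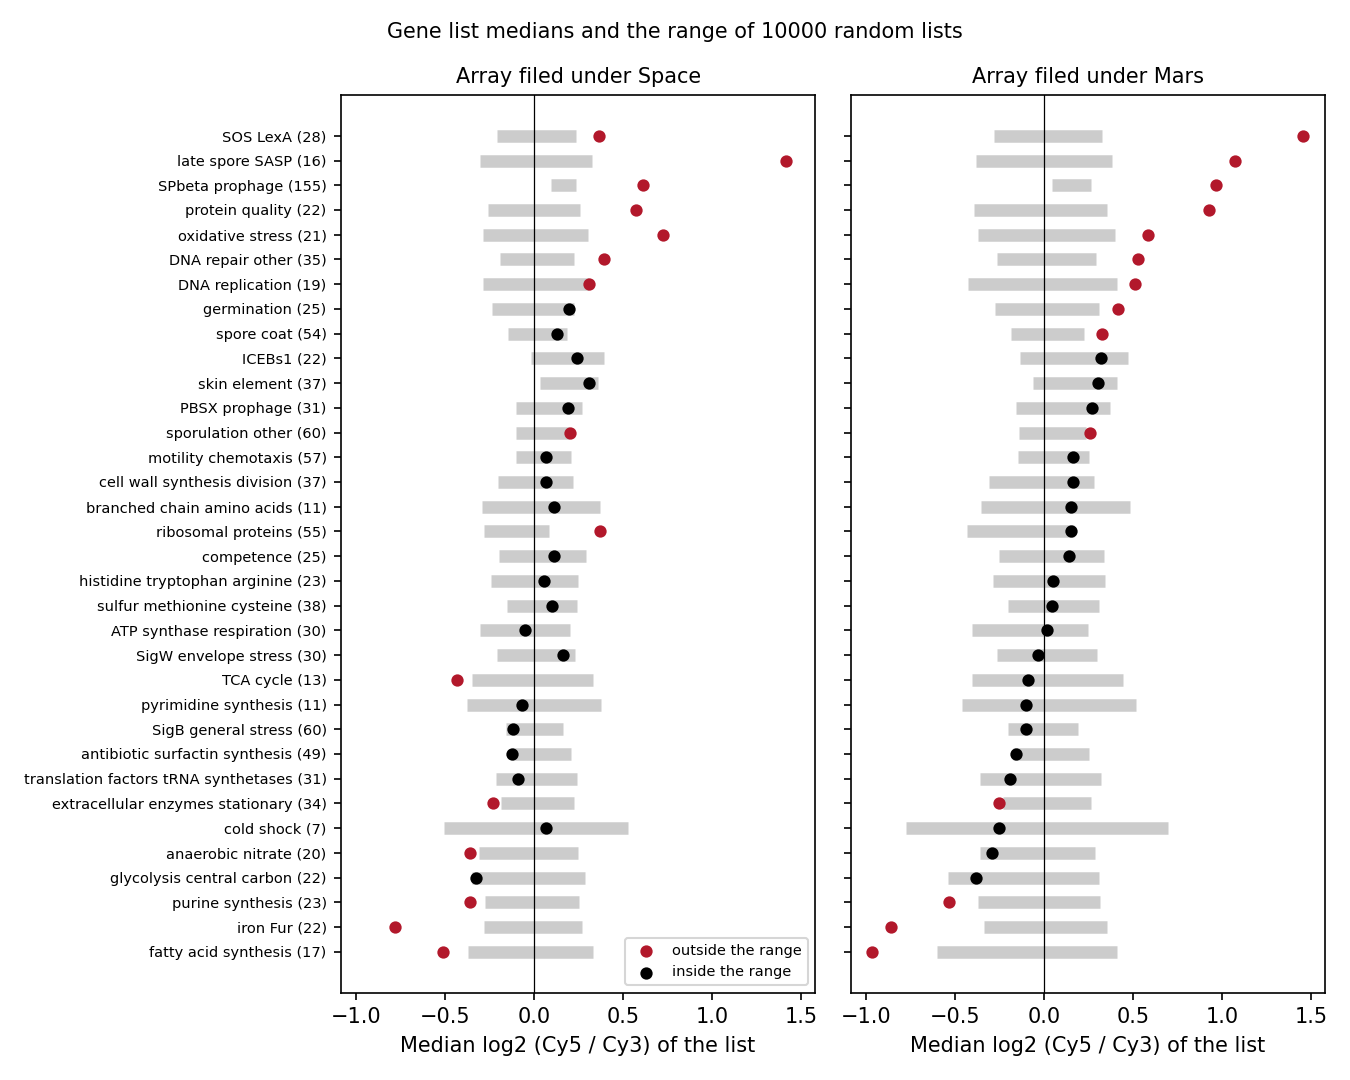
Median log2 ratio of Cy5 over Cy3 (horizontal axis) of each gene list with its number of measured genes (vertical axis) on the Space-filed (left) and Mars-filed (right) array. Gray bars span the random range, the central 95% of 10000 random lists matched on signal, and red points lie outside them, such as the SOS list at 0.37 and 1.46 and the iron list at -0.78 and -0.86.

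Of the gene lists, the SOS genes had the largest median difference between the arrays, being further toward Cy5 on the Mars-filed array, except with median centring, where that of SP-beta was larger (-0.81 against -0.73). The 5 largest Space-filed minus Mars-filed differences of single genes lay in the polYB region, and were -4.64 ± 0.23 for yqjY, -4.55 ± 0.10 for yqjX, -4.55 ± 0.26 for yqjZ, -4.47 ± 0.29 for polYB and -4.36 ± 0.28 for yqkA. The SOS list had a median difference of -0.84 (random range -0.13 to 0.15), with 12 of 28 genes at least 2-fold apart, including uvrA (-2.05 ± 0.14) and recA (-1.73 ± 0.08). Of genes higher on the Space-filed array, the largest differences were in ganR, a regulator of galactan use (1.55 ± 0.20), yqcK (1.40 ± 0.13), yddR (1.30 ± 0.65), sspE (1.25 ± 0.20) and the arsenic repressor gene arsR (1.22 ± 0.27). This order depended on the processing, and with the authors' value table matched to the scanner files arsR was the largest of them at 2.37, followed by yddR (1.89), yqcK (1.77), ganR (1.62) and sspE (1.25). With median centring sspE (1.43) and ganR (1.40) stayed past 2-fold, while yqcK (0.78), yddR (0.69) and arsR (0.52) fell below it. In all, 88 of 4072 genes were at least 2-fold apart, 26 higher and 62 lower on the Space-filed array, but at 1.5-fold 218 were higher and 197 lower. With the scanner software's background the count at 2-fold was 152, with 69 higher and 83 lower.

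SP-beta genes had a median difference of -0.26, with 26 of 155 lower on the Space-filed array, such as yonU (-2.22 ± 0.17) and yonX (-1.53 ± 0.41), and 6 higher. This median was -0.56 with the scanner software's background. The gene spbT, outside the list, differed by -3.11 ± 0.18. Fatty acid genes had a median difference of 0.50, with fabI at 1.01 ± 0.28. Smaller median differences outside the random range were found for other repair genes (-0.19), replication (-0.29), germination (-0.27) and coat (-0.24). The same held for the tricarboxylic acid cycle (-0.20) and SigW (0.19), each within it under 2 of 12 alternatives, and for antibiotics (-0.13) and purines (0.17), within it under 6. The differences of protein quality control (-0.16), anaerobic genes (-0.15) and respiration (-0.06) also lay outside the range, but these turned positive with median centring (0.032, 0.00013 and 0.021). Oxidative stress genes had a median difference of -0.07 within the range, although 7 of 21 were lower on the Space-filed array, among them mrgA (-1.71 ± 0.23), hemX (-1.51 ± 0.10) and hemA (-1.40 ± 0.07).

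Overlap between the arrays was counted per direction. Of the genes at least 2-fold apart, 213 were higher in Cy5 on both and 77 lower on both, among them clpE, the fru operon and sspN, and 0 went opposite ways. Independent lists of these sizes would share 23.3 higher and 5.79 lower, and the simulated unchanged samples against 1 shared control shared 79.3 and 77.2. Those simulated ratios were symmetric. Their lists were not matched to the observed sizes, which for lower genes were 97 on the Space-filed and 243 on the Mars-filed array. The simulated counts therefore cannot show how much of the overlap a shared control alone would give. Ratios correlated across 4072 genes with r = 0.873 and rho = 0.871, where genes are not independent replicates, against r = 0.50 in the simulation. The covariance was 0.503 against a simulated 0.228, a difference of 0.275. The simulated r and covariance follow from the settings, which gave all samples equal spread and took the whole variance of the Space-filed ratios as noise. They therefore cannot show how much of the correlation a shared control alone would give. Part of the overlap may come from a shared control. A dye effect common to both arrays could add to it and is not in the simulation. With 1 array per group and no dye swap these parts cannot be split. The SD of ratios was 1.26 times as large on the Mars-filed array, and 327 genes were past 2-fold only there, against 61 only on the Space-filed array, a contrast set by the threshold and not tested.

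**Figure D3:**
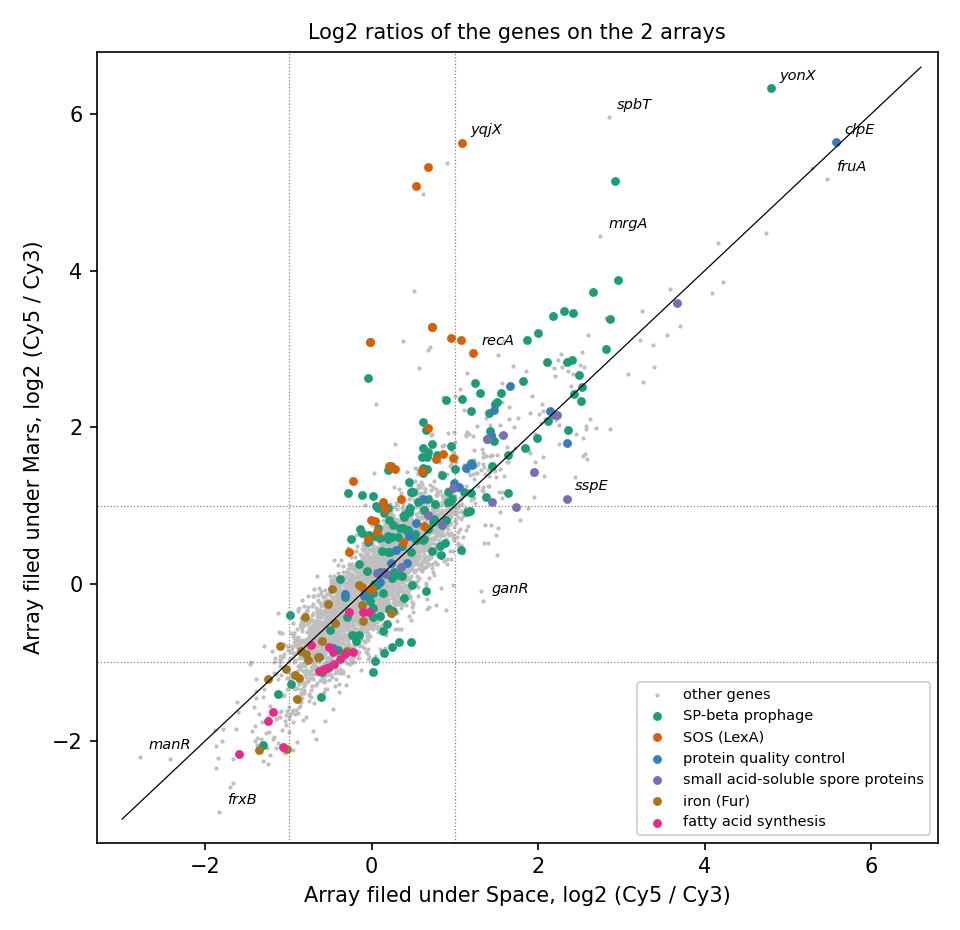
Log2 ratio of Cy5 over Cy3 of each gene on the Space-filed (horizontal axis) against the Mars-filed array (vertical axis), with 6 gene lists in color, the line of equal ratios and dotted lines at 1 and -1. Ratios correlate with r = 0.873, and all but 1 of the 28 SOS genes lie above the line of equal ratios, as yqjX does at 1.09 and 5.64.

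The channels themselves differed in how alike the arrays were. After loess and scaling of mean signals, the Cy3 signals of the 2 arrays differed with an SD of 0.15 (log2, 95% bootstrap interval over genes 0.144 to 0.157), where duplicate spots alone would give 0.14, and 2 of 3889 genes were over 2-fold apart. The Cy5 signals differed with an SD of 0.41 (0.379 to 0.437), where duplicate spots would give 0.17, and 65 of 3670 genes were over 2-fold apart. For 27 SOS genes the Mars-filed minus Space-filed median was 0.82 in Cy5 and -0.17 in Cy3. For the SP-beta genes well above background in a channel it was 0.017 over 87 genes in Cy5 and -0.028 over 71 in Cy3, which leaves out the dim members. The Space-filed minus Mars-filed ratio had medians of -0.26 for these 87 genes and -0.14 for these 71, against -0.31 and -0.40 for the other 68 and 84. It was negative for 54 of the 87 and 38 of the 71, and for 46 of the 68 and 62 of the 84. No random range was made for these subsets.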

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

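The tests on the dye channels and on the spore transcripts were chosen after the result was seen. Predictions for the planned tests on the SOS genes were written before those tests were run, but the pattern they address came from these same data. The regulator genes ganR and arsR lay on opposite sides of 0 on the 2 arrays by more than the SD between their spots, with Space-filed minus Mars-filed differences of 1.55 and 1.22. With median centring they were 1.40 and 0.52, the latter below 2-fold, and with the scanner software's background 1.64 and 2.60. These differences were not tested. Spike-in control probes, left out of the comparisons, were brighter than negative controls by 2.60-fold in Cy3 and 2.93-fold in Cy5 on the Space-filed array, and by 1.20-fold and 1.28-fold on the Mars-filed array.

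The Cy3 signals of the 2 arrays were alike and the Cy5 signals were not. The labels put Earth RNA in Cy5 on both arrays, but 1 common Earth RNA there is argued against by an SD between arrays of 0.37 beyond duplicate spots. Dye labels that were turned, with 1 Earth RNA in Cy3, would give a low SD in Cy3, and the Cy3 SD beyond duplicate spots was 0.063. That value is the pattern itself and adds no support, so this reading stays open. Separate Earth cultures that differed from each other in Cy5 stay open, since they too could give the 65 genes over 2-fold apart there. That reading also requires the Space and Mars RNA, both in Cy3 as labelled, to be alike, with 2 of 3889 genes over 2-fold apart. These readings cannot be told apart with 1 array per exposure.

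The SOS genes were further apart on the Mars-filed array. Compression of ratios by the brighter background of the Space-filed array was checked on the 19 members with above-median signal. Their median difference was still -0.83, outside the random range of -0.15 to 0.19. Those random lists were matched on signal but not on size of ratio, so that range alone cannot decide. Outside the SOS and SP-beta lists, 24 genes had a Mars-filed log2 ratio of at least 3. Their median difference was -0.19 (from -4.47, for polYB, to 0.41), which argues against compression of large ratios in general. The loess fit is argued against by a median difference of -0.73 with median centring. A difference between the exposures, or between cultures, stays open as a hypothesis and was not tested. The SOS difference lay mainly in Cy5. The Mars-filed minus Space-filed median was 0.82 there over 27 genes, and -0.17 in Cy3. With the dyes as labelled, that would be mainly a difference between the Earth controls. A difference between the exposures in Cy5 would need the dye labels to be turned. The exchanged labels also leave open which exposure such a difference may belong to.

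Late spore transcripts were higher in Cy5 on both arrays. For dim spots, the small acid-soluble spore protein genes had a median of at least 1.07, above the range of random lists of like signal. This is the same comparison that showed the pattern, so it adds no separate support against that explanation. RNA from spores that had not germinated in the Cy5 sample may contribute. The check made for this assumed that the coat genes would then be higher too. These data cannot show whether that assumption holds, so the check cannot decide the question. The median of all 54 coat genes was 0.13 on the Space-filed array, within the random range, and 0.33 on the Mars-filed array, above it. Subsets formed after the values were seen lay above their random ranges on both arrays. Medians were 1.11 and 1.19 for 15 late coat genes and 0.71 and 0.62 for 7 early ones. The test was first made on the late subset and then widened to the whole list, also after the values were seen, and the question is undecided. Which sample that was follows from the unsettled dyes, and no biological explanation was tested.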

How the results depend on the processing

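The value table matched to the scanner files was added after seeing the data. No paired analysis was possible because there was 1 array per group and the labels carry no replicate numbers, and leaving out a replicate was not possible for the same reason. The correlation between arrays stayed between 0.867 and 0.890 under all alternatives, and the number of list medians outside the random range, 29 of 68 over both arrays, ranged from 28 to 33. Dropping or tightening the filter on dim probes, taking the mean over probes, keeping outlier spots, not asking probes to agree and leaving out background subtraction moved no count by over 1.5 times. On the Space-filed array, between 84.1% and 100% of the genes called were called again with the same sign under alternatives at 2-fold that kept the array labels, and on the Mars-filed array between 82.6% and 100%. What depth limits is the dim end: 13 calls on the Space-filed and 3 on the Mars-filed array had 1 channel not above background.

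The cause of the changes that follow was not tested, except that a lower or higher fold size by construction counts more or fewer genes. At 1.5-fold the Space-filed count was 1111 (625 higher, 486 lower), the Mars-filed count 1556 (835 and 721) and the count between arrays 415 (218 and 197). At 3-fold they were 126 (110 and 16), 257 (185 and 72) and 20 (0 and 20). The scanner software's background gave 152 genes between arrays, 69 of them higher on the Space-filed array, and an offset of 0 gave 50 higher. Median centring gave 1005 on the Mars-filed array (600 and 405) and 96 lower on the Space-filed array in the comparison between arrays. The software's log ratio gave 164 lower genes on the Space-filed and 383 on the Mars-filed array, and 147 between arrays, with 55 higher. The value table as labelled gave 809 for Space (429 and 380) and 151 between Space and Mars, with 95 higher. Matched to the scanner files, it gave 163 lower on the Space-filed and 382 on the Mars-filed array, and 151 between arrays (56 and 95).

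Median centring turned the differences between arrays for protein quality control to 0.032, respiration to 0.021 and anaerobic genes to 0.00013, and respiration turned to 0.021 with the software's log ratio and with the matched value table. The value table as labelled turned the differences between Space and Mars, because its columns are exchanged. It gave 0.84 for the SOS list, 0.15 for other repair, 0.71 for SP-beta, 0.14 for protein quality control, -0.19 for SigW, -0.18 for purines, 0.18 for the tricarboxylic acid cycle, 0.15 for anaerobic genes, 0.23 for coat, 0.26 for germination, 0.26 for replication, -0.55 for fatty acids and 0.13 for antibiotics. Among genes it gave -1.89 for yddR, -1.25 for sspE, 4.48 for yqkA, 4.59 for yqjZ, 4.67 for yqjY, 4.53 for yqjX, 4.58 for polYB, -1.77 for yqcK, -2.37 for arsR and -1.62 for ganR. For Space over Earth it gave -0.24 for yqcK and -0.27 for ganR.

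Of 12 alternatives, the replication list stayed outside the random range under 6 on the Space-filed array, as did the differences between arrays of respiration, antibiotics and purines. Extracellular and transition-state genes on the Mars-filed array stayed outside under 8, falling within with the scanner software's background, no background subtraction, the software's log ratio and the matched value table. The difference between arrays stayed outside under 10 for the tricarboxylic acid cycle, not without background subtraction or with unmatched random lists, and under 10 for SigW, not without background subtraction or with median centring. For anaerobic genes it stayed outside under 9. The iron, SOS, SP-beta, oxidative stress, protein quality control, small acid-soluble spore protein, purine and fatty acid lists stayed outside on both arrays under all 12. Median centring also put motility (0.65) and ribosomal protein genes (0.44) on the Mars-filed array and coat genes (0.34) on the Space-filed array above the range, antibiotic genes below it on both arrays (-0.13 and -0.09), and other sporulation genes on the Space-filed array (0.28) within it. Random lists not matched on signal put the skin element above the range and glycolysis below it on both arrays.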

Other observations

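Neighbouring genes stood apart together in blocks. This search of gene order, and the genes named from it, were chosen after the values were seen. At least 4 neighbours in a row were 2-fold higher in Cy5 on both arrays in 14 places, with 78 genes, and 0 such blocks were lower on both. Of these blocks 9 held members of the fixed lists, with 43 such genes, and 5 held none. The block of sigV, the lysozyme-responsive sigma factor, with rsiV, oatA and yrhK had medians of 2.09 and 2.29 on the Space-filed and Mars-filed arrays. A block from etfA to mutSB, with the fatty acid degradation genes fadB, fadR and lcfA, had medians of 2.07 and 1.54. The blocks yhbI to yhcC (2.27 and 2.77), yrkI to yrkE (2.55 and 1.76) and ndhF to ybcI (1.42 and 2.14) lay outside every list, as did that of sigV. The heme genes hemE, hemH and hemY stood with yhgD and yhgE at medians of 1.22 and 1.89.

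Blocks lower in Cy5 on the Space-filed array held manR, manP, manA and yjdF (median -1.94), bglH and bglP of beta-glucoside use with yxxE and rtbE (median -1.17), and yybN to yybJ (median -1.39). The same genes had medians of -2.04, -1.47 and -1.44 on the Mars-filed array, where manP (-0.99), bglH (-0.76) and, by less than rounding, yybM missed 2-fold. The Mars-filed array had 7 such blocks, including yydD, yydC, yydB and rlmH (median -2.13) and the autolysin genes lytC, lytB and lytA with tagU (median -1.12). Its largest block higher in Cy5 ran over 20 genes from yosT to yorZ, all but dutB in the SP-beta list (median 2.51), and a block of 10 genes from yqkE to yqzH around polYB had a median of 3.98 against 0.68 on the Space-filed array.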
